A study of Mus musculus with 8 samples.

How the data were processed

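RNA from RAW264.7 cells, a mouse macrophage-like line, was sequenced after culture on polyetheretherketone (PEEK), a polymer used for bone implants, whose surface was either smooth or structured at the nanometre and micrometre scale. There were 4 libraries per surface and 8 in all. Per the labels' protocols, messenger RNA was selected on oligo(dT) beads, the second strand was marked with dUTP, adapters carried molecular identifiers, and the libraries were sequenced as read pairs of 150 bases each. Adapters were trimmed with cutadapt 1.9 and reads aligned with HISAT2 2.2.1, per the submitters' processing notes. The counter, its strand setting, any use of the molecular identifiers, the annotation and the genome build are not given in the sources used here.

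The authors deposited 1 table of 26848 genes with an estimated count and an FPKM value per gene and library, and with gene positions, GO terms and KEGG pathways. The deposited expected counts are whole numbers, rounded by the authors, and are not plain fragment counts. Low values pile up at multiples of 4: the value 4 occurred 8018 times over the 8 libraries, against 3344 times for 3 and 2180 times for 5, and of the values from 1 to 40, 32.1% were multiples of 4, against 25.3% from 400 to 4000. A unit of 75 covered bases would give 4 units per fragment of 2 reads of 150 bases. On that reading 1 fragment counts as 4 units in the library totals of 64479829 to 73098735 units. The FPKM values were normalized to gene length and library depth by the authors, per the file headers. The ratio of count to FPKM gave the same length per gene, within 1% in all libraries, for 99.9% of genes with a mean count above 500. Of the 26848 genes, 26779 were found in GENCODE M21 and 24140 had identical coordinates there, so positions are printed as the table gives them, without a build stated by the authors.

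The design fixed before the data were examined named limma on log2(FPKM + 0.5) as the test, and edgeR on counts in its place if the table also held whole-number counts. The table held them, so edgeR 4.0.16 under R 4.3.3 gave the main result: filterByExpr with a minimum count of 10, TMM scaling, and the two-sided quasi-likelihood test of structured minus smooth with Benjamini-Hochberg adjustment at 0.05. It tested 16006 genes and left out 10842 with low counts. CPM values are counts divided by the TMM-scaled library size and multiplied by 1e6. The 40 gene lists fixed beforehand were tested with camera of limma 3.58.1 (correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the 37 lists with at least 5 tested members. The result of 1 of these lists is not reported here, though counts of lists include it. The same test was run on 3218 GO terms and 303 KEGG pathways of 10 to 500 tested genes. A floor of 3 fragments, or 12 count units over a group, stands for a group in which every library was at 0. Intervals and floors cover counting error alone.

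Genes were named by a rule fixed beforehand. It took the 10 highest and 10 lowest fold changes among genes past the threshold with a mean FPKM of at least 5 in either group, groups that did not overlap and a symbol that was not a clone or predicted name. From each list it took up to 4 members past the threshold with the smallest p, or the most abundant member where none passed. It also took 22 genes by name, whatever their result. This gave 113 genes, and 29 more were added after their values were seen. Those 29 were chosen in part because libraries differed in them, and further genes looked at in the same way were dropped. Counts over named genes are therefore given for the 113 alone. Markers of skeletal muscle (21 genes), hepatocytes (23) and neutrophils (24 measured) were written as lists after the data had been seen.

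Alternatives fixed beforehand were other filters, DESeq2 size factors, quantile normalization, voom with and without library weights, DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 0.5, 0.1 and 1, a replicate block, a fold threshold, each library left out in turn, and other set tests. Alternatives chosen after seeing the data were counts divided by 4, removal of the trend with GC content and exon length (known for 99.9% of tested genes), leaving out 3 libraries together, and the hepatocyte transcript level as a covariate. The mixed test of fry has no direction, and after its result was seen it was compared with the main result by its side of the threshold alone. On counts simulated for structured against smooth with 1 unit per fragment, over 15530 genes, the edgeR step recovered 99.0% of 100 genes changed by 1 and 44.0% of 100 changed by 0.3 on the log2 scale, and called 9 of 15330 unchanged genes. With 4 units per fragment, over 15450 genes, it recovered 96.0% and 35.0%, and called 10 of 15250. Over 15513 genes with a simulated GC trend, removing the trend lowered the unchanged genes called from 3391 to 13. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.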

Results

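Gene expression was measured in RAW264.7 macrophage-like cells cultured on smooth or on nano- and microstructured PEEK, 4 libraries per surface. The series concerns surface topography and the immune environment at bone implants, and the comparison asks which genes differ between the surfaces. Totals were 65771871, 71185448, 64479829 and 73098735 count units in smooth 1 to 4. They were 69086629, 68070668, 69885018 and 64660379 in structured 1 to 4, and 3 fragments in a library correspond to 0.164 to 0.186 CPM. The labels number biological replicates but do not state separate cultures or days, so the p-values measure the spread between these samples, which may be technical. Correlations of log2 CPM between libraries ran from 0.968 to 0.982 within a group and from 0.968 to 0.979 between groups.

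Of 16006 genes tested, 161 rose and 440 fell on the structured surface (edgeR with Benjamini-Hochberg adjustment), most of them by little. The median log2 fold change was 0.25 among genes that rose and -0.24 among genes that fell, and 32 rose and 4 fell by at least 1 on the log2 scale. Anpep, an aminopeptidase of the myeloid cell surface, fell from 102.7 ± 6.34 to 67.5 ± 3.73 CPM (SD, n = 4 per group), a log2 fold change of -0.60 ± 0.05 (SE; edgeR BH-adjusted p = 6.4e-04). Rusc2, an adaptor of vesicle traffic, fell by 0.52 ± 0.04 on the log2 scale. Fnip2, a folliculin partner, fell by 0.42 ± 0.04 and Slc6a8, a creatine transporter, by 0.50 ± 0.06. Esyt1 (-0.47), C77080 (-0.43) and Usp2, a deubiquitinase (-0.42), were also among the 10 lowest fold changes of the naming rule, which takes genes with a mean FPKM of at least 5 in either group and groups that did not overlap. Other called genes outside that rule fell by more. Among genes that rose under the same rule were Mir17hg, host of a microRNA cluster (0.62 ± 0.11), the mitochondrial nuclease gene Endog (0.58 ± 0.13), and Zbtb32 (0.45 ± 0.08). Ube2l6, an ISG15-conjugating enzyme (0.46 ± 0.10), Parp9 (0.38 ± 0.08) and the pseudogene Ncoa4-ps (0.36 ± 0.08), whose reads can be shared with its parent gene, rose as well. The groups did not overlap for 593 of the 601 called genes, and for 12.2% of all tested genes, where chance gives 2.86%.

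Fewer genes were called with each library left out in turn. Fewer samples enter these fits, so the lost calls do not show that a single library carried the result. The median log2 fold change of genes called lower in the main test stayed at -0.255 to -0.229, against -0.240 in the main test. For genes called higher it stayed at 0.236 to 0.266, against 0.248. These genes were chosen by their folds in the same libraries. Without smooth 2, 3 or 4 there were 240, 166 and 219 calls, and without structured 1, 2 or 4 there were 306, 125 and 88, each more than 1.5 times fewer than 601. Of 82 called genes named by the fixed rule, 21 kept their call with each library left out in turn, namely Anpep, C77080, Chil3, Fnip2, Fth1, Grn, Hexa, Hmox1, Hsp90ab1, Hspa5, Jun, Lcn2, Mmp8, Npc1, Oas2, Osgin1, Piezo1, Ptk2b, Rusc2, S100a9 and Slc6a8. The other 61 lost it at least once: 58 without structured 4, 55 without structured 2, 43 without smooth 3, 39 without smooth 2, 39 without smooth 4, 33 without structured 1, 18 without smooth 1 and 11 without structured 3. Lower calls made up 73.2% of calls, but 61.4% with DESeq2, 62.3% with the hepatocyte transcript level as a covariate and 55.4% with the trend on GC content and exon length removed. That removal ended the call of 26 of the 82 genes, 18 of which kept at least 0.75 of their log2 fold change. Among these were Plk1 (-0.16 before and -0.17 after), Bag3 (-0.22 and -0.21), Slc39a10 (0.23 and 0.22), Zc3h12a (-0.26 and -0.24), Ube2l6 (0.46 and 0.41), Ncoa4-ps (0.36 and 0.29), Car2, Laptm5, Slc11a1 and Zmat3. The other 8 were Hk1 (-0.16 and -0.06), Tln1 (-0.22 and -0.11), Piezo1 (-0.25 and -0.14), Sdhd (0.22 and 0.14), Lyz1 (0.29 and 0.19), Foxm1, Clcn7 and Gaa. Atp2a1 (-2.70 and -2.67) and Ern1 (-0.28 and -0.23), named after their values were seen, also lost it.

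**Figure D1:**
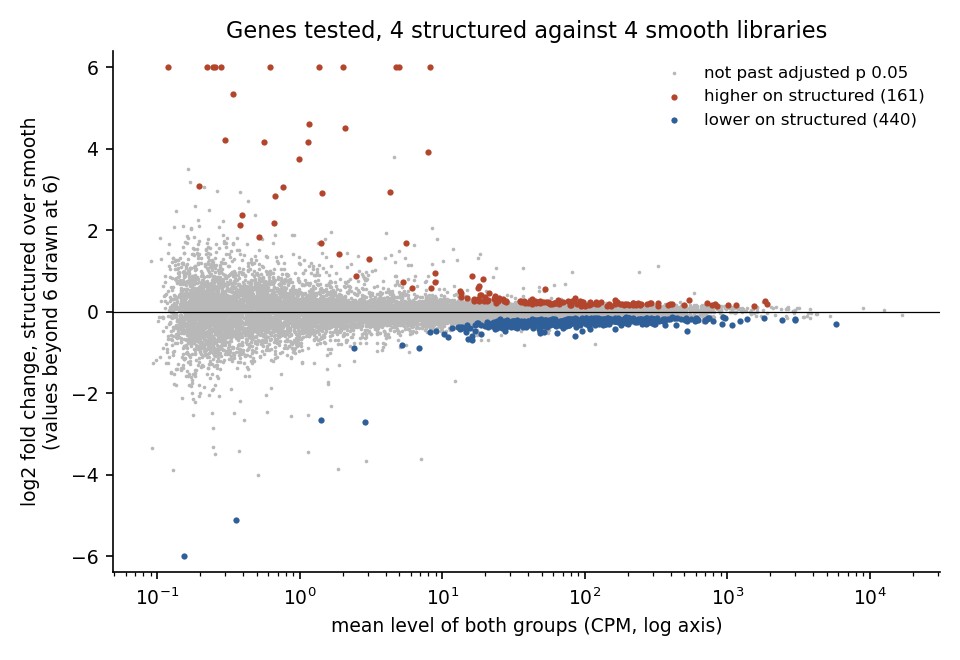
Log2 fold change of structured over smooth PEEK (values beyond 6 drawn at 6) against the mean level of both groups in CPM on a log axis, 1 point per tested gene, with the 161 higher genes in red and the 440 lower genes in blue. Most called genes lie within 1 of 0 on the log2 scale.

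Positions in the deposited table were chromosome 7, 79821803 to 79848210, for Anpep (ENSMUSG00000039062) and chromosome 4, 43381979 to 43427088, for Rusc2 (ENSMUSG00000035969). They were chromosome 5, 120730333 to 120749853, for Oas2 (ENSMUSG00000032690) and chromosome 2, 34771970 to 34777547, for Hspa5 (ENSMUSG00000026864). Nos2 and Chil3 lie on chromosome 11, 78920787 to 78960254, (ENSMUSG00000020826), and chromosome 3, 106147554 to 106167564 (ENSMUSG00000040809). Counts are sums over whole genes, with no exon or UTR resolved.

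Of 29 tested type I interferon response genes 5 rose, and 14 were higher when adjusted over the list alone. The median log2 fold change was 0.56, and 28 members had positive values. Oas2, which senses double-stranded RNA, rose from 11.5 ± 1.57 to 20.9 ± 4.02 CPM (SD, n = 4 per group), a log2 fold change of 0.86 ± 0.14 (SE; edgeR BH-adjusted p = 0.0123). Oas3 of the same family (0.81 ± 0.15), Rtp4 (1.30 ± 0.25), the RNA sensor Ddx58 (0.51 ± 0.11) and Oasl2 (1.42 ± 0.30, named after its values were seen) rose too. Whether reads were shared between genes of the Oas family was not examined. The camera adjusted p was 8.3e-11, against adjusted p = 0.538 with an estimated correlation and 0.0560 with fry's directional test, and alternatives ran from 1.4e-14 to 0.538. Oas2 kept its call with each library left out. Oas3 lost it without structured 2 or structured 4, Oasl2 without smooth 3, smooth 4, structured 1, 2 or 4, and Rtp4 and Ddx58 without these or smooth 2. The highest edgeR BH-adjusted p of the 4 without 1 library was 0.0987. The median rise over the smooth mean was 0.66, 0.72, 0.18 and 0.64 in structured 1 to 4, and structured 2 to 4 also held the highest levels of several neutrophil transcripts, described further on.

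Lists of translation, sterol synthesis and the cell cycle had positive medians. None of 73 cytosolic ribosomal protein genes passed alone, also when adjusted over the list alone, with 24 at an unadjusted edgeR p under 0.05, 16 called by DESeq2 and 1 by voom. Rpl4 had a log2 fold change of 0.09 ± 0.03 (SE), and 0.02 with the GC and length trend removed. Their median was 0.09 (camera adjusted p = 8.3e-08, and adjusted p = 0.538 with an estimated correlation; alternatives from 1.4e-10 to 0.538). In cholesterol biosynthesis 5 of 24 members rose, and 9 when adjusted over the list alone. Acat2 rose by 0.27 ± 0.05, Cyp51, the lanosterol demethylase, by 0.25 ± 0.06, the farnesyl diphosphate synthase gene Fdps by 0.22 ± 0.05, Ebp by 0.19 ± 0.05 and Stard4, named after its values were seen, by 0.22 ± 0.06 (n = 4 per group). That list had a camera adjusted p of 6.2e-05, and adjusted p = 0.538 with an estimated correlation, with alternatives from 2.2e-06 to 0.538. Ebp and Stard4 lost their calls without any 1 of the 8 libraries, Cyp51 without each but smooth 3, Fdps without smooth 1, smooth 4, structured 1, 2 or 4, and Acat2 without smooth 3 or structured 2. With the GC and length trend removed Cyp51, Ebp and Stard4 had log2 fold changes of 0.23, 0.15 and 0.21 and edgeR BH-adjusted p-values of 0.0508, 0.104 and 0.0884, and the 5 genes ranged from 2.0e-05 to 0.157 over the alternatives. In DNA replication, Fen1, which processes Okazaki fragments, rose by 0.23 ± 0.04, the only 1 of 36. There were 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.4e-04, and adjusted p = 0.538 with an estimated correlation, with alternatives from 2.2e-05 to 0.538). Mitosis genes were split, with Kif20a up by 0.18 ± 0.04 and Plk1 (-0.16 ± 0.04) and Foxm1 (-0.20 ± 0.05) down. Of 35, 6 were higher and 3 lower when adjusted over the list alone (median 0.06). The mitosis list had a camera adjusted p of 0.0134, 0.0767 without smooth 1, and adjusted p = 0.538 with an estimated correlation. Its alternatives ran from 6.2e-04, by fry's mixed test, to 0.538. In oxidative phosphorylation Sdhd rose by 0.22 ± 0.05 and Uqcrc1 fell by 0.16 ± 0.04, 1 each of 34, also when adjusted over the list alone (median 0.05). Its camera adjusted p was 0.0478, and adjusted p = 0.617 with an estimated correlation, 0.396 without smooth 3, 0.0796 without smooth 4, 0.221 without structured 2, 0.0894 without structured 4 and 0.775 with the GC and length trend removed. Its alternatives ran from 0.00707 to 0.775.

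In the unfolded protein response 5 of 24 members rose and 1 fell, and 9 rose and 3 fell when adjusted over the list alone. Hspa5, the main chaperone of the endoplasmic reticulum, rose from 1686 ± 51.8 to 2011 ± 73 CPM (SD, n = 4 per group), a log2 fold change of 0.25 ± 0.03 (SE; edgeR BH-adjusted p = 0.00689), and kept its call with each library left out. Pdia6 (0.22 ± 0.04), Canx (0.16 ± 0.03), Creld2 (0.24 ± 0.05) and Hsp90b1 (0.18 ± 0.04) rose, while the stress sensor gene Ern1 fell by 0.28 ± 0.06; Hsp90b1 and Ern1 were named after their values were seen. Hsp90b1 lost its call without smooth 2, structured 1, 2 or 4, and Ern1 without these, smooth 3 or smooth 4 (edgeR BH-adjusted p up to 0.104). The camera adjusted p was 0.0179, and adjusted p = 0.538 with an estimated correlation and 0.0604 without smooth 4. Alternatives ran from 9.5e-05, by fry's mixed test, to 0.538. Of 16 heat shock genes none rose by edgeR, DESeq2 or voom, with 4 at an unadjusted edgeR p under 0.05 in either direction, and Hsp90ab1 (-0.19 ± 0.03) and Bag3 (-0.22 ± 0.05) fell, also when adjusted over the list alone (camera adjusted p = 0.375).

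**Figure D2:**
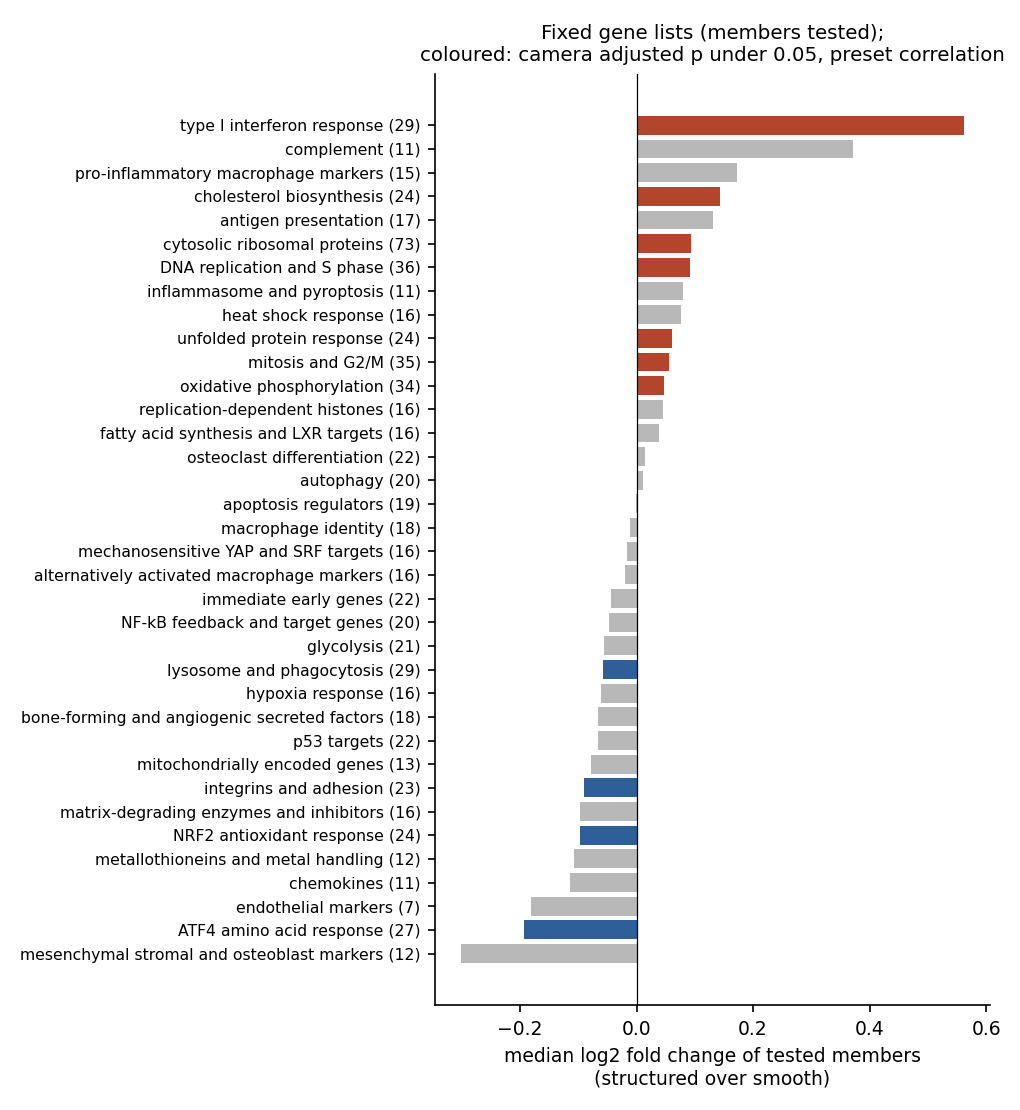
Median log2 fold change of structured over smooth PEEK for the reported fixed gene lists with at least 5 tested members, the number tested in parentheses. Bars are red (higher) or blue (lower) where camera with the preset correlation called the list and grey where it did not. Interferon response genes had the highest median of the called lists, 0.56.

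Of 27 members of the ATF4 amino acid response, which serves amino acid supply, 5 fell, and 9 when adjusted over the list alone. Slc7a11, a cystine transporter, fell by 0.43 ± 0.09, Shmt2 by 0.20 ± 0.04, Slc3a2 by 0.25 ± 0.06, Slc7a5 by 0.29 ± 0.07 and Trib3, named after its values were seen, by 0.69 ± 0.17 (SE, n = 4 per group). That list had a camera adjusted p of 4.3e-05, and adjusted p = 0.538 with an estimated correlation, with alternatives from 7.5e-09 to 0.538. Of 24 NRF2 antioxidant genes 5 fell, and 8 when adjusted over the list alone. Hmox1, which degrades haem, fell from 411 ± 27.8 to 325 ± 15.8 CPM (SD). Osgin1 fell by 0.63 ± 0.09, Fth1, the ferritin heavy chain gene, by 0.30 ± 0.04 and Sqstm1 by 0.24 ± 0.04, with Slc7a11 shared between both lists. The NRF2 list had a camera adjusted p of 0.00153, and adjusted p = 0.538 with an estimated correlation, with alternatives from 2.5e-05 to 0.538. Hmox1, Osgin1 and Fth1 kept their calls with each library left out. The 5 ATF4 genes each lost their call without smooth 3, smooth 4, structured 1, structured 2 or structured 4, and Shmt2, Slc3a2, Slc7a5 and Trib3 also without smooth 2 and Trib3 without smooth 1. With the GC and length trend removed Shmt2, Slc3a2, Slc7a5 and Trib3 had log2 fold changes of -0.17, -0.23, -0.24 and -0.69 and edgeR BH-adjusted p-values of 0.0532, 0.0654, 0.0731 and 0.0569, and the 5 genes ranged from 1.3e-05 to 0.133 over the alternatives.

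Of 29 lysosome and phagocytosis genes 6 fell, and 8 when adjusted over the list alone. Grn, the progranulin gene, fell from 605 ± 34.0 to 437 ± 34.5 CPM (SD, n = 4 per group), a log2 fold change of -0.47 ± 0.06 (SE; edgeR BH-adjusted p = 0.00434). Npc1, which exports cholesterol from lysosomes, fell by 0.33 ± 0.04, the hexosaminidase gene Hexa by 0.29 ± 0.04 and the glucosidase gene Gaa by 0.25 ± 0.04. The camera adjusted p was 0.00399, and adjusted p = 0.538 with an estimated correlation and 0.0834 with the hepatocyte transcript level as a covariate. Alternatives ran from 3.1e-05, by fry's mixed test, to 0.538. Grn, Npc1 and Hexa kept their calls with each library left out, and Gaa reached an edgeR BH-adjusted p of 0.0614 without structured 2 or structured 4 and 0.0569 at a log2 fold change of -0.18 with the GC and length trend removed, within a range of 2.2e-05 to 0.0614 over the alternatives.

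Of 23 integrin and adhesion genes 3 fell, and 5 when adjusted over the list alone. Ptk2b, an adhesion kinase, fell by 0.31 ± 0.04, Tln1, which couples integrins to actin, by 0.22 ± 0.04 and Itgb7 by 0.33 ± 0.08 (SE, n = 4 per group). The camera adjusted p was 0.0134, and adjusted p = 0.538 with an estimated correlation, 0.20 with the GC and length trend removed and 0.0802 with the hepatocyte covariate. Its alternatives ran from 4.8e-04, by fry's mixed test, to 0.538. With the trend removed Tln1 went to -0.11 (edgeR BH-adjusted p = 0.126) and Itgb7 to -0.30 (0.0654), and over the alternatives both ranged from 2.3e-06 to 0.140. Itgb7 lost its call without each library in turn but structured 3, and Tln1 without structured 2 or structured 4. Of 16 YAP and SRF targets only Piezo1, a mechanically gated channel, passed (-0.25 ± 0.04; also the only 1 when adjusted over the list alone; camera adjusted p = 0.503), and with the trend removed its edgeR BH-adjusted p was 0.0649, within a range of 9.6e-09 to 0.0758 over the alternatives.

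Markers of macrophage activation moved in no shared direction. Of the pro-inflammatory markers, 15 tested, Nos2, the inducible nitric oxide synthase gene, fell from 82.6 ± 7.34 to 64.4 ± 4.70 CPM (SD, n = 4 per group; log2 fold change -0.36 ± 0.07; edgeR BH-adjusted p = 0.0214, up to 0.0779 without smooth 3, structured 2 or structured 4, and 2.2e-05 to 0.123 over the alternatives). Fpr2, a formyl peptide receptor, rose from 0.133 to 1.83 CPM, and 2 markers were higher and 2 lower when adjusted over the list alone. The cytokine gene Tnf had a log2 fold change of 0.05 ± 0.05 (0.0026 with the trend removed; edgeR BH-adjusted p = 0.672), Il1b 1.89 ± 0.50 at about 1 CPM (0.0603) and Cd86 -0.65 ± 0.46 (0.514). Of 16 alternatively activated markers Chil3 rose and Tgfb1 fell by 0.19 ± 0.04 (edgeR BH-adjusted p = 0.0324, lost without each library in turn but smooth 1 and structured 3, 0.0676 at -0.15 with the trend removed, and 3.5e-04 to 0.107 over the alternatives), the same 1 and 1 when adjusted over the list alone. Arg1 had 0.69 ± 0.59 and Il1rn -0.14 ± 0.07. That list's median was -0.02, its mean 0.65 and its camera direction down. Chil3 was near 0 on smooth PEEK, at 1.24 CPM in structured 1 and at 18.4 to 26.0 CPM in structured 2 to 4. Its adjusted p ran from 4.4e-08 to 0.409 over the alternatives, and voom called no member of that list higher. The camera adjusted p was 0.400 for the first list and 0.731 for the second. Il6 and Mrc1 were at 0.109 and 0.147 CPM on smooth and 0.105 and 0.207 CPM on structured PEEK, too low to test. Il10 was at 0 in every smooth library and at least 4.79-fold higher on structured PEEK, at 0.211 ± 0.0858 CPM (SD, n = 4), and was not tested.

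Among factors that act on bone and vessels, 18 tested, Tgfb1 and Sema4d, a semaphorin (-0.31 ± 0.05), fell, with 4 lower and 1 higher when adjusted over the list alone (median -0.07, mean 0.03, camera down with adjusted p = 0.544). With an FPKM of at least 5 in 4 or more libraries as the filter, the camera adjusted p of this list was 0.0436. Vegfa had -0.32 ± 0.09 (edgeR BH-adjusted p = 0.0888), Pdgfb -0.15 ± 0.08, Osm -0.01 ± 0.10 and Spp1 0.05 ± 0.04 (SE, n = 4 per group). With the trend removed Pdgfb had -0.09 and Spp1 turned to -0.05. Bmp2 at 0.0988 and 0.0768 CPM was too low to test. Of 22 osteoclast genes Car2 rose by 0.19 ± 0.04, and Jun (-0.31 ± 0.04) and Clcn7 (-0.20 ± 0.05) fell, with 1 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.888). Acp5 had 0.16 ± 0.08, Ctsk -0.23 ± 0.08 and Nfatc1 0.02 ± 0.04. With the trend removed Ctsk passed at -0.31 (edgeR BH-adjusted p = 0.0482, 0.0334 to 0.371 over the alternatives), and Nfatc1 had 0.09. Jun kept its call with each library left out. Of the reference genes, Actb had -0.17 ± 0.04 (edgeR BH-adjusted p = 0.0523, 0.0290 with the trend removed, and 0.00303 to 0.295 over the alternatives), Gapdh 0.17 ± 0.08, Hprt 0.04 ± 0.06, -0.07 with the trend removed, and B2m 0.01 ± 0.04, -0.12 with the trend removed.

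**Figure D3:**
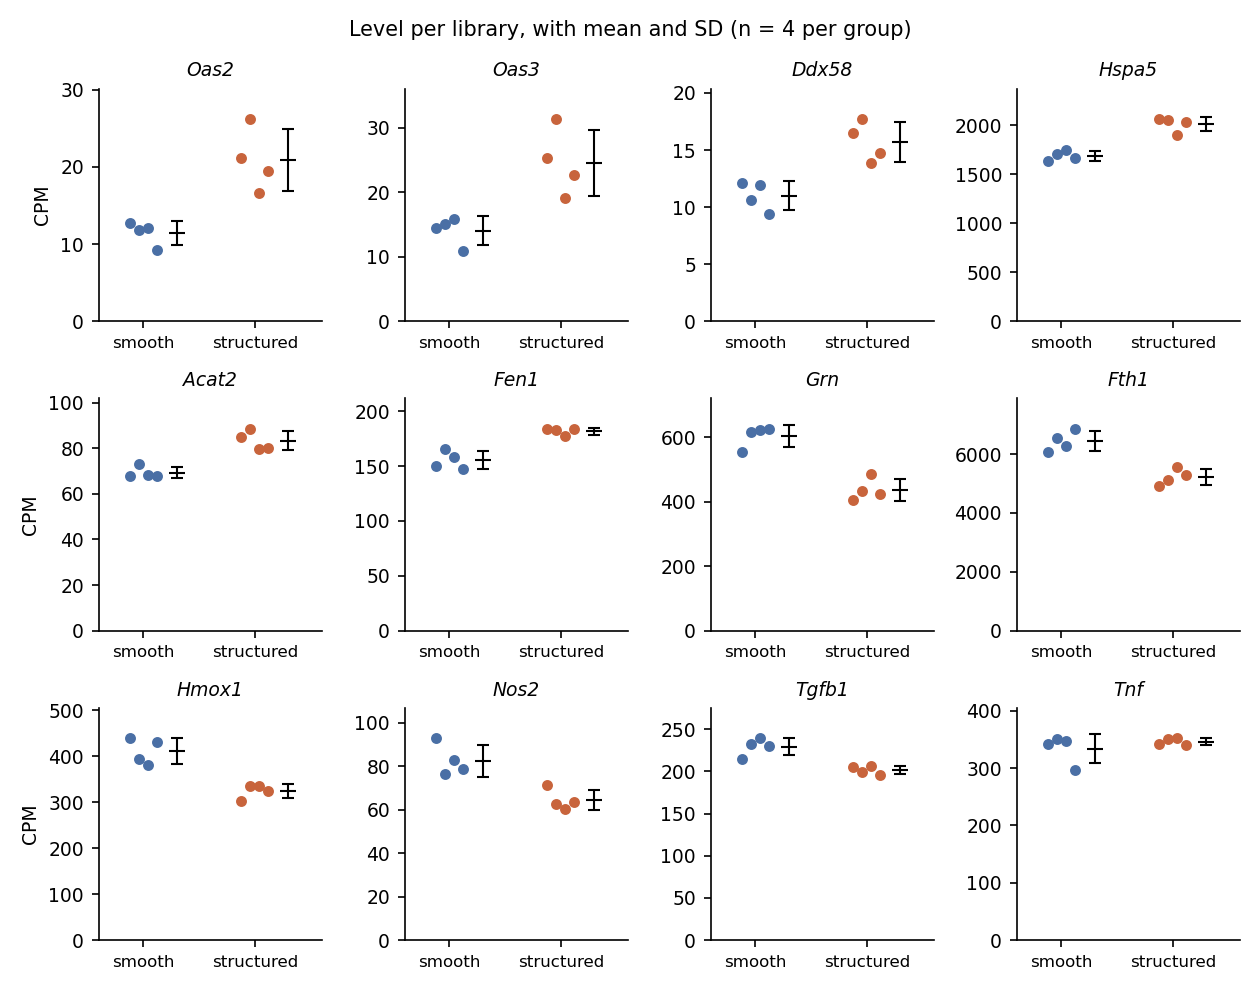
CPM per library of 12 named genes on smooth and structured PEEK, 1 point per library, with bars for the mean and SD of 4 libraries. Nos2 averaged 82.6 CPM on smooth and 64.4 CPM on structured PEEK.

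Further lists were not called by camera in the main test. Of 22 immediate early genes Jun, Atf3 (-0.54 ± 0.13) and Zfp36 (-0.28 ± 0.06) fell, the same 3 when adjusted over the list alone. That list had a camera adjusted p of 0.224, and of 0.0251 with an FPKM of at least 5 in 4 or more libraries as the filter. Slc2a1 (-0.21 ± 0.05) and Hk1 (-0.16 ± 0.04) fell among 21 glycolysis genes (3 higher and 8 lower when adjusted over the list alone), and Ndrg1 (-0.47 ± 0.08) among 16 hypoxia genes (2 lower). Likewise fell Trp53 (-0.19 ± 0.04), Plk2 (-0.33 ± 0.06) and Zmat3 (-0.21 ± 0.05) among 22 p53 targets (5 lower), and Bcl2l11 (-0.28 ± 0.06) among 19 apoptosis regulators (2 higher and 1 lower). So did Zc3h12a (-0.26 ± 0.06) among 20 NF-kB genes (1 higher and 5 lower) and Sqstm1 among 20 autophagy genes (1 lower). H2-K1 (0.23 ± 0.05) rose among 17 antigen presentation genes (1 higher when adjusted over the list alone). That list had a camera adjusted p of 0.0700, and of 0.0403 without structured 4. Its alternatives ran from 1.7e-05, by fry's mixed test, to 0.538. Slc39a10 (0.23 ± 0.06) rose and Slc11a1 (-0.25 ± 0.05) and Fth1 fell among 12 metal-handling genes (2 higher and 6 lower). Lyz1 (0.29 ± 0.06) rose, with reads that its copy Lyz2 can share, and Cx3cr1 (-0.22 ± 0.04) and Laptm5 (-0.20 ± 0.04) fell among 18 macrophage identity genes (2 higher and 3 lower; SE, n = 4 per group). By edgeR no member passed over all genes among 11 chemokines (Ccl3 -0.17 ± 0.06, and -0.28 with the trend removed, edgeR BH-adjusted p = 0.0373, 0.0316 to 0.627 over the alternatives; 1 higher and 1 lower when adjusted over the list alone). None passed either way among 11 inflammasome genes (Txnip 0.08, 0.05 with the trend removed, and camera adjusted p = 0.258, 0.0337 without smooth 4, 0.0403 without structured 4, and over the alternatives 0.0107, by fry's mixed test, to 0.701), 16 fatty acid and LXR genes (Fads2 0.09) or 16 histone genes (H1f0 0.20). At an unadjusted edgeR p under 0.05 there were 3, 1, 3 and 2 members of these 4 lists, and DESeq2 called 2, 1, 1 and 1 and voom none. The same held for 13 mitochondrially encoded genes (mt-Co1 -0.08, and -0.19 with the trend removed, edgeR BH-adjusted p = 0.0355, 0.0355 to 1.00 over the alternatives; camera adjusted p = 0.184, 0.0321 without smooth 1, 0.0447 without structured 4, 9.6e-08 to 0.980 over the alternatives) and 12 stromal genes (Sparc 0.11). It held for 7 endothelial genes (Eng -0.16, -0.10 with the trend removed; camera adjusted p = 0.180, 0.0413 without structured 2, 0.0413 to 0.902 over the alternatives) and 4 lymphocyte genes (Ighm -0.01). At an unadjusted edgeR p under 0.05 there were 1, 0, 1 and 0 members, and none was called by DESeq2 or voom. Median, mean and camera direction differed in sign for chemokines (-0.11, 0.05, down), apoptosis regulators (-0.001, 0.01, up), fatty acid genes (0.04, -0.02, down), autophagy (0.01, 5.1e-04, down) and matrix enzymes (-0.10, 0.66, down). Complement genes, 11 tested with none past the threshold in edgeR or voom, 3 at an unadjusted edgeR p under 0.05 and 1 called by DESeq2 (Cfp 0.20 ± 0.06), stood highest in smooth 1, structured 3 and structured 4, the libraries with most hepatocyte transcripts. The complement list had a camera adjusted p of 0.400, and of 0.0446 without a filter on low counts.

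Transcripts of other cell types differed between libraries. The 24 listed neutrophil genes summed to 62.6, 66.2, 71.1 and 68.9 CPM in smooth 1 to 4 and to 73.1, 137, 137 and 147 CPM in structured 1 to 4. Mmp9, which macrophages also express, made up at least 53.3 CPM of each smooth sum. Mmp8, a neutrophil collagenase listed among 16 matrix enzymes (1 higher; 3 higher and 3 lower when adjusted over the list alone), was at 0 in every smooth library and at least 214-fold higher on structured PEEK, at 0.75, 12.2, 12 and 12.8 CPM in structured 1 to 4. Ngp, a granule protein gene, was at least 90.8-fold higher. Over the alternatives the adjusted p ran from 1.4e-11 to 0.263 for Mmp8 and from 2.7e-05 to 0.223 for Ngp. For S100a9, a calgranulin gene, it ran from 1.1e-10 to 0.139. None of the matrix enzymes was called by voom. Chil3 and S100a9, a calgranulin gene, each had 1 fragment over the smooth libraries, and their ratios of structured to smooth were 1102 (95% counting interval 197 to 43577) and 675 (121 to 26703). S100a8, S100a9 and Ngp were the 3 of 4 tested neutrophil and mast cell markers that rose, also when adjusted over the list alone, and DESeq2 called 1 of the 4 and voom none. Lcn2, of the innate response to bacteria, rose from 0.998 ± 0.557 to 15.0 ± 2.70 CPM (SD, n = 4 per group), with 11.1 CPM in structured 1. Of genes named after their values were seen, Saa3, an acute-phase gene, rose by 2.93 ± 0.16, Fpr1 by 4.60 ± 0.53, Il1f9 by 3.06 ± 0.63, Thbs1 by 4.17 ± 0.74 and F10 by 2.90 ± 0.52 (log2, SE). Saa3 and Fpr1 kept their calls with each library left out. Il1f9 lost it without smooth 3, smooth 4, structured 1, 2 or 4, F10 without smooth 2, smooth 4 or structured 4, and Thbs1 without smooth 3 or structured 4 (edgeR BH-adjusted p up to 0.0819). Chil1 and Igkc, both at 0 on smooth PEEK, were at least 62.5-fold and at least 12.8-fold higher.

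Hepatocyte transcripts, 23 genes led by Alb, summed to 454, 141, 135 and 94.2 CPM in smooth 1 to 4 and to 195, 193, 373 and 650 CPM in structured 1 to 4. Alb itself did not pass (log2 fold change 0.66 ± 0.47; edgeR BH-adjusted p = 0.524). Skeletal muscle transcripts summed to 108, 68.9, 58.5 and 78.6 CPM in smooth and to 63.1, 59.5, 55.2 and 56.6 CPM in structured libraries. Of these sums Eno3, Tnni2 and Myoz1, set apart after their values were seen, made up 44.6 to 54.2 CPM in every library, and the other 18 genes 57.7, 18.2, 13.9 and 33.2 CPM in smooth and 12.2, 5.28, 3.55 and 3.99 CPM in structured 1 to 4. Ckm, the muscle creatine kinase gene, fell by 2.65 ± 0.54 and Atp2a1 by 2.70 ± 0.64 (log2, SE, n = 4 per group), and Tcap was at least 6.95-fold lower, all named after their values were seen. Atp2a1 lost its call without each library in turn but structured 1 (edgeR BH-adjusted p up to 0.131), Ckm without smooth 4, structured 2 or structured 4, and Tcap without these or smooth 3. The epithelial keratin genes Krt8 and Krt18, the 2 tested of that list, had 1.88 each (edgeR BH-adjusted p = 0.118 and 0.109), and both were higher when adjusted over the list alone. Without smooth 1, structured 3 and structured 4, a choice made after seeing the data, 62 genes were higher and 124 lower.

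**Figure D4:**
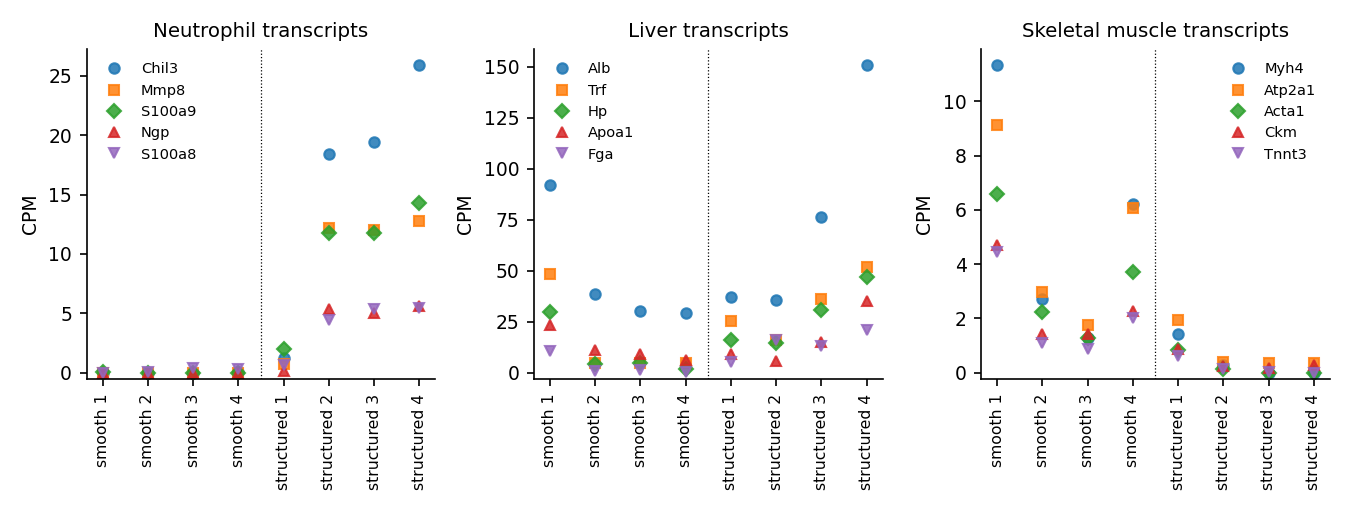
CPM of 5 marker transcripts each of neutrophils, liver and skeletal muscle in each library, 1 symbol per gene, with a dotted line between smooth and structured libraries. Alb reaches 91.9 CPM in smooth 1, 76.4 CPM in structured 3 and 151 CPM in structured 4, against at most 38.6 CPM in the others.

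Of 3521 GO terms and KEGG pathways, camera called 78 up and 123 down, and with an estimated correlation 0, with 315 at an unadjusted p under 0.05, where the smallest adjusted p among the leading terms was 0.552. Ribosome, proteasome core complex (median log2 fold change 0.13), DNA replication and cellular response to interferon-beta (0.17) were among the 10 leading terms up. Actin binding (-0.08, 2 higher and 26 lower of 287 genes), Lysosome (1 higher and 16 lower of 116), glycosaminoglycan degradation (-0.19) and SMAD binding (-0.09) were among the 10 leading terms down.

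Calls followed GC content and gene length. From the fifth of tested genes with the lowest GC content to that with the highest (medians 41.1 to 57.6%), 18, 37, 77, 144 and 164 genes fell and 22, 41, 48, 30 and 20 rose. From the fifth with the shortest exons to that with the longest (medians 865 to 9076 bases), 9, 44, 57, 122 and 208 fell and 23, 51, 34, 33 and 20 rose.

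**Figure D5:**
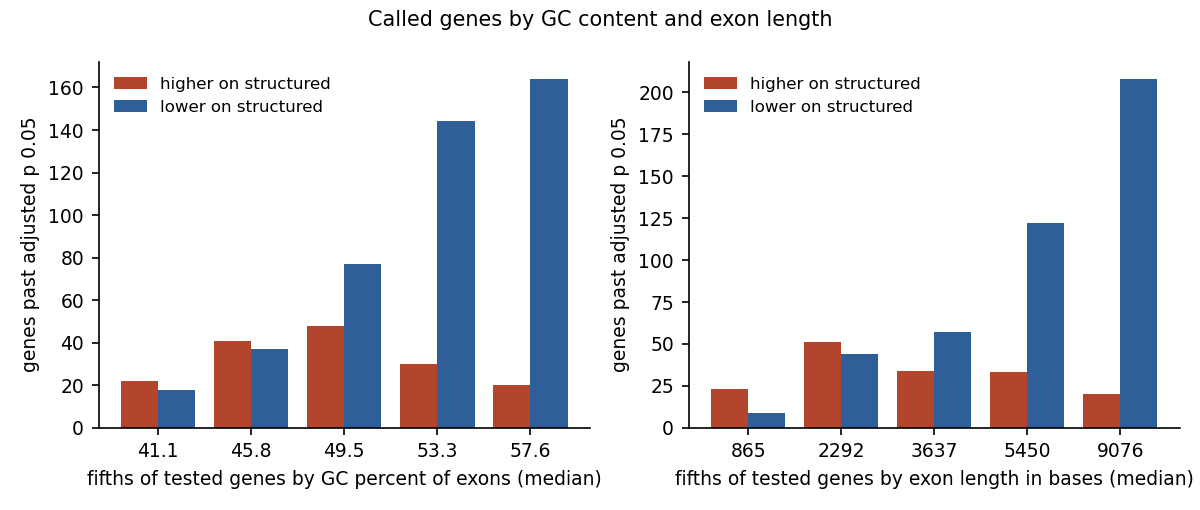
Number of genes past the threshold, higher in red and lower in blue, in 5 equal groups of tested genes by GC percent of exons and by exon length in bases, each group marked with its median. Lower calls rise from 18 to 164 along GC content and from 9 to 208 along length.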

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

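Tests of the excess of lower calls, of neutrophil reads and of the RAW264.7 response were chosen after the results were seen. A library stood far from the other 3 of its group, by Dixon's criterion at 95%, in 33 of 289 groups of 4 values, where chance gives about 1 in 20, or 14.4. The check first covered the 237 groups without genes added later, 22 of which stood out against 11.8 by chance. It was widened afterwards to 52 groups of added genes, 11 of which stood out, and since several of those genes were picked because libraries differed, the wider count overstates the pattern. A gene found in only 1 library of a group meets the criterion in any case, and genes of the same libraries can vary together. Both counts are therefore a rough guide.

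Smooth 1 stood apart for hepatocyte transcripts (454 CPM, the others up to 141), Alb (91.9), Trf (48.4), Hp (29.7), Fga (10.8) and Apoe (59.3), for F10 (0.796), Camp (0.225), S100a9 (0.0601) and Eng (23.7), and low for Grn (554 CPM). Smooth 2 was high for Acat2 (73.01) and Hsp90ab1 (3253), and smooth 4 for the share of counts in its 10 most abundant genes (7.54%) and Chil3 (0.0693), and low for Ebp (37.9) and Tnf (296). Camp, S100a9 and Chil3 were at 0 in the other smooth libraries, so they met the criterion whatever their level. S100a9 and Chil3 had 1 fragment each on smooth PEEK. Structured 1 was low for neutrophil transcripts (73.1 CPM in sum, the others at least 137), Mmp8 (0.75), Ngp (0.159) and Atf3 (11.4), and high for the muscle genes Ckm (0.851), Atp2a1 (1.95) and Acta1 (0.822). Structured 2 was low for Hk1 (182) and high for Cyp51 (114), Acp5 (31.7) and Ctsk (42.7), and structured 3 was high for Jun (85.2), Zfp36 (82.8) and Ltf (0.298) and low for mt-Co1 (15413) and Creld2 (130 CPM).

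Of 20 neutrophil markers with a mean under 0.5 CPM on smooth PEEK, 16 lay above all smooth libraries in each of structured 2, 3 and 4, with S100a9 at 11.7 to 14.3 CPM there and 1.99 CPM in structured 1. Random lists matched on level gave 7 at the 95% point, but the markers were listed after neutrophil genes had been seen to differ, so the count describes the pattern and does not test its source. Neutrophil reads or RNA remain a candidate source. Granule genes differed: Camp and Ltf, of maturing neutrophils, were below 0.3 CPM in every library. Ngp was at 0.159 CPM in structured 1 and at 4.99 to 5.57 CPM in structured 2, 3 and 4. A response of the RAW264.7 cells remains open as well, since structured 1 held 0.158 of the marker level of the others but is a single library. The labels name a cell line and no other cell type, and these sources cannot be told apart.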

How the results depend on the processing

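Alternatives chosen after seeing the data were counts divided by 4, removal of the GC and length trend, leaving out smooth 1, structured 3 and structured 4 together, and the hepatocyte covariate. No gene called in the main test was called in the opposite direction under any setting run. Calls of genes (601 in the main test, 161 higher and 440 lower) came to 189 (47 and 142) without a filter on low counts, 1433 (553 and 880) with DESeq2, which left 5280 adjusted p-values undefined, and 389 with limma on log2 FPKM at each pseudocount, with 254 lower at 0.5 and 1 and 255 at 0.1. With a log2 fold change of at least 1 they came to 36 (32 and 4), by construction. The 3 libraries left out together gave 186 (62 and 124), the hepatocyte covariate 369 with 230 lower, and the trend removed 225 lower. Leaving out 1 library gave 88 to 597 calls, 21 to 170 higher and 67 to 427 lower; fewer samples enter these fits, and for the other changes the cause was not tested. The remaining alternatives stayed within 1.5 times of the main counts.

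Of the fixed lists 12 were called, against 0 with an estimated correlation (1 at an unadjusted p under 0.05, by camera), 1 with fry's directional test, 29 with its mixed test, 11 to 13 with 1 library left out, 8 with the hepatocyte covariate, 10 with the replicate block and 15 without a filter on low counts. Of the GO terms and pathways 201 were called, against 0 with an estimated correlation (315 at an unadjusted p under 0.05), where camera allows for genes that vary together. Over the 113 genes of the naming rule, alternatives gave the same call 1877 times, a lost call 548 times, a gained one 25 times and 0 reversals. Over the 29 genes added later they gave 391, 108 and 16, and 1 reversal, Apoe with the hepatocyte covariate (-0.41, adjusted p = 0.0417; main 0.22; adjusted p from 0.0417 to 0.978 over the alternatives); the cause was not tested. Over lists they gave 891, 59, 32 and 0.

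With the replicate block there were 499 calls, 125 higher and 374 lower, and 2 lists lost their camera call, among them the unfolded protein response (0.0511). The numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.06, 0.08, -0.00 and -0.16, and 1 of 4 correlated best with its own number. Depth limits genes near 0.164 to 0.186 CPM, the level of 3 fragments in a library.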

Other observations

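The test of the excess of lower calls against GC content and length, and the tests of transcripts of other cell types, were chosen after the results were seen. Of the 35 splits of the libraries into 4 and 4, 1, the real one, gave counts as large. For genes it gave 601 calls against at most 2 in any other split, 161 higher against 2 and 440 lower against 2. For terms it gave 201 against up to 103, so camera with the preset correlation called many terms in a split that mixes the surfaces. A share of 1 in 35 is the smallest that these splits can give. Mixed splits also hold any difference between the surfaces as spread within groups, so chance is not excluded by them. For the lists the real split also called most, but by 12 against 10, so camera with the preset correlation called nearly as many lists in splits that mix the surfaces, and the number of lists by itself is weak evidence.

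Many genes were lower by small folds, and lower calls outnumbered higher ones. With the trend on GC content and exon length removed, the median of the 440 lower genes went from -0.24 to -0.19. This was 0.781 of its size (bootstrap interval over genes 0.758 to 0.822). The 440 were chosen by their folds in these same libraries, and part of the size that stayed can come from that choice. The interval leaves out the spread between libraries, so the share does not decide for or against the trend. Of the 440, 181 stayed called, and the 259 others went from a median of -0.22 (quartiles -0.26 and -0.19) to -0.15 (-0.19 and -0.11) with standard errors of 0.0461 and 0.0449, 255 of them to a smaller fold and 65 to a larger standard error. The excess itself went with the trend: 55.4% of calls were lower after its removal, which is consistent with a trend of technical or biological origin, and these data do not separate the origins. Counts divided by 4 left 438 of the 440 called lower. Only 5 of the 440 were under 5 CPM in both groups, and dividing large counts by a constant changes their folds little. The number of units per fragment thus mattered little to these calls, and how the counts were derived was not tested. DESeq2 size factors moved the share of lower calls by 2.74 percentage points. They moved the median of all genes only from 0.00564 to 0.00865, too little to exclude scaling.

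The median log2 fold change of interferon response genes was 0.56. Removing the GC and length trend left 0.933 of the list's median (bootstrap interval over genes 0.840 to 1.06), so the fitted trend took away little of it. The interval leaves out the spread between libraries and treats members as independent, though their estimated correlation was 0.252. The share therefore does not decide against the trend. Camera called the list under both of the 2 other scalings. A factor per library moves all genes alike, so it cannot set a list apart from other genes. The list's median was 0.566 with DESeq2 size factors and 0.522 with quantile normalization. For all tested genes it was 0.00865 and 0.00567. For a factor per library this outcome was fixed in advance, so the fit with DESeq2 size factors does not test scaling. Quantile normalization also left the list's median above that of all genes. Neutrophil reads cannot be told apart from a change in the RAW264.7 cells. Structured 1, low in neutrophil transcripts, rose by 1.28 times the mean of structured 2, 3 and 4, but it is a single library. Structured 3 lowered that mean: its neutrophil transcripts summed to 137 CPM, yet its rise was the smallest, at 0.18. Structured 2 and 4 were high in both, with rises of 0.72 and 0.64. A response to the surface also stays open, as untested.

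Hepatocyte markers had smooth 1, structured 3 and structured 4 as their 3 highest libraries in 19 of 23 cases, against 2 at the 95% point of random lists. Smooth 1 alone of the smooth libraries lay above a structured one in hepatocyte level. Smooth 2, 3 and 4, at 94.2 to 141 CPM, lay below every structured library, at 193 CPM or more. A single library cannot exclude a response to the surface. Muscle markers lay higher in smooth 1 than in each of structured 2, 3 and 4 in 19 of 21 cases, against 10 at the 95% point of random lists. The marker lists were written after such genes had been seen, so these counts describe the patterns and do not test a source.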
